A study of Mus musculus with 15 samples.

How the data were processed

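Lungs of 15 female Crlj:CD1(ICR) mice, an outbred stock, were profiled on 1-colour Agilent mouse expression arrays after 7 days on diets with 0, 20, 500, 2500 or 5000 ppm permethrin. Each diet had 3 mice, each array held the RNA of 1 mouse, and per the labels the 3 arrays of a diet are biological replicates. Per the labels, Cy3 cRNA was made from 100 ng of total RNA. Per the file headers, the scans were read with Agilent Feature Extraction 10.7.3.1, and the scanner files hold the background-subtracted processed signal and the median spot and background signals as intensity on a linear scale. The deposited table holds log2 values. On every array these had a correlation of 1 with log2 of the processed signal and differed from it by 1 constant per array.

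The values reported here start from the processed signal in the scanner files. Control spots were left out, and replicate spots of a probe were averaged, which gave 56605 probes. The log2 signal of each array was set so that its 75th percentile over these probes was 0. A probe was kept when it was well above background, by the software's own call in at least 50% of its spots, on all 3 arrays of at least 1 diet, and 43154 probes were kept. Probes were named through their RefSeq accession and a table of the GRCm38.p6 assembly, which was used for symbols only. The file headers give mm9 as the build of the probe coordinates. For each symbol the kept probe with the highest mean over the 15 arrays was used, and probes without a symbol stayed as features of their own. This left 34401 features, 19289 of them with a symbol. They are called genes here. Probes known only by other identifiers (21930 on the array) carried no symbol.

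Groups were compared with limma 3.58.1 in R 4.3.3, with 1 coefficient per diet over all 15 arrays, default empirical Bayes settings and 10 residual degrees of freedom per gene. Contrasts were each dose against control, 5000 against 2500 ppm, a trend over the 5 dose ranks, and an F test for any difference among the 5 diets. P values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, with a threshold of 0.05. Errors are standard errors (SE) from this model unless named SD, and all tests were two-sided. Gene lists on xenobiotic metabolism, oxidative stress, stress responses, growth, inflammation and the cell types of the lung and its neighbours (43 lists, 835 of their 870 distinct members measured) were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 43 lists. The correlation estimated from the data and limma's fry were run beside it. The lists were tested at each dose and on the trend, and the list test for 5000 against 2500 ppm was added after the data were seen. Fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. Members were also counted as adjusted over the list alone. Fold changes at pairs of doses share the same 3 control arrays, so their correlation was set beside 100 simulations of unchanged groups measured against a shared control.

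The groups, contrasts, gene lists, thresholds and most alternatives were fixed before the data were examined, as was the rule for naming genes. At 2500 ppm, 5000 ppm and on the trend the rule takes, among genes past the threshold whose 3 treated mice all lay on 1 side of the 3 controls, the 12 largest rises and the 12 largest falls. At the other contrasts it takes the 5 largest of each. Where none passes, it takes the 3 genes with the smallest p. It adds members of each list whose test passed (up to 4 past the threshold, or else the 2 with the largest fold at 5000 ppm), and 12 genes named in every case: Cyp2b10, Cyp2f2, Scgb1a1, Cyp1a1, Cyp3a13, Por, Nr1i3, Nr1i2, Mki67, Top2a, Sftpc and Foxj1. Bare model names and unnamed probes are outside the rule, and 1 list member that the rule takes is not reported here. Genes named outside it are said to be chosen after their values were seen.

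The alternatives were normexp background correction on the median signals with an offset of 50, quantile normalization, the array median as the scale, the deposited values, no filter, a filter over all 15 arrays, every probe by itself, the mean of a gene's probes, the replicate number or the slide as a block, empirical Bayes with a trend and robust settings, array weights, only the groups compared, a log2 fold of at least 1 beside the threshold, other dose scales and each array left out in turn. Normexp had been planned on mean spot signals, which the files do not hold. Like-numbered arrays of control and 20 ppm deviated together from their group means (r 0.612, 0.261 and 0.166 for mouse 1, 2 and 3), but so did control mouse 2 with 20 ppm mouse 3 (r 0.374) and control mouse 3 with 20 ppm mouse 2 (r 0.375). Like-numbered arrays deviated together as well at 500 and 2500 ppm (r 0.382, 0.289 and 0.475). So did 500 ppm mouse 1 with 2500 ppm mouse 2 (r 0.25) and 500 ppm mouse 2 with 2500 ppm mouse 1 (r 0.203). The like-numbered pairs of each other pair of diets included r under 0.1. For 9 of 15 arrays the best partner in another diet had the same number. Deviations of 3 arrays from their mean cancel, so 1 array far from the others in each of 2 diets can also give such values. The equal numbers are at most a hint from the data, not from the labels, and control and 20 ppm were also fitted as pairs. A block for the scan day was not run, since all arrays were scanned on 1 day. The fit was tested on simulated data, drawn from each gene's mean and residual SD with 200 genes changed by known folds. At 5000 ppm it found 10.4% of genes changed 1.5-fold, 40.3% of those changed 2-fold and 74.2% of those changed 4-fold. At 2500 ppm these shares were 1.49%, 29.9% and 56.1%, at 500 ppm 4.48%, 38.8% and 66.7%, at 20 ppm 2.99%, 35.8% and 78.8%, for 5000 against 2500 ppm 4.48%, 25.4% and 65.2%, and on the trend 5.97%, 41.8% and 80.3%. Each share comes from 1 draw with 66 or 67 changed genes. All doses were drawn with the same residual SDs and group sizes, so differences between the shares of the doses are those of the draw. The number of arrays limits the precision of every value.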

Results

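RNA was measured in the lungs of 15 female mice, 3 on each of 5 diets with 0 (control), 20, 500, 2500 or 5000 ppm permethrin for 7 days. Permethrin is a pyrethroid insecticide that acts on voltage-gated sodium channels. The share of probes well above background ran from 70.8% to 87.0% of an array, and no array had saturated spots. The arrays lay on 2 slides. Slide 1 held the 3 control arrays, the 3 arrays at 20 ppm and 2 at 500 ppm, and slide 2 held the third array at 500 ppm and all arrays at 2500 and 5000 ppm. Slide and dose were therefore confounded for 2500 and 5000 ppm against control, apart from 1 array. The first principal component (35.61% of variance) set apart 500 ppm mouse 3 (score 185.5) and 2500 ppm mouse 3 (score 76.62), the 2 arrays whose files hold an extraction status of 1, against 0 in the others. The second component (22.38% of variance) set apart control mouse 1 (score -113.4) and 20 ppm mouse 1 (score -107.4). Over all genes the median change was 0.10 (log2) at 500 ppm, and list results below compare members with all other genes.

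**Figure D1:**
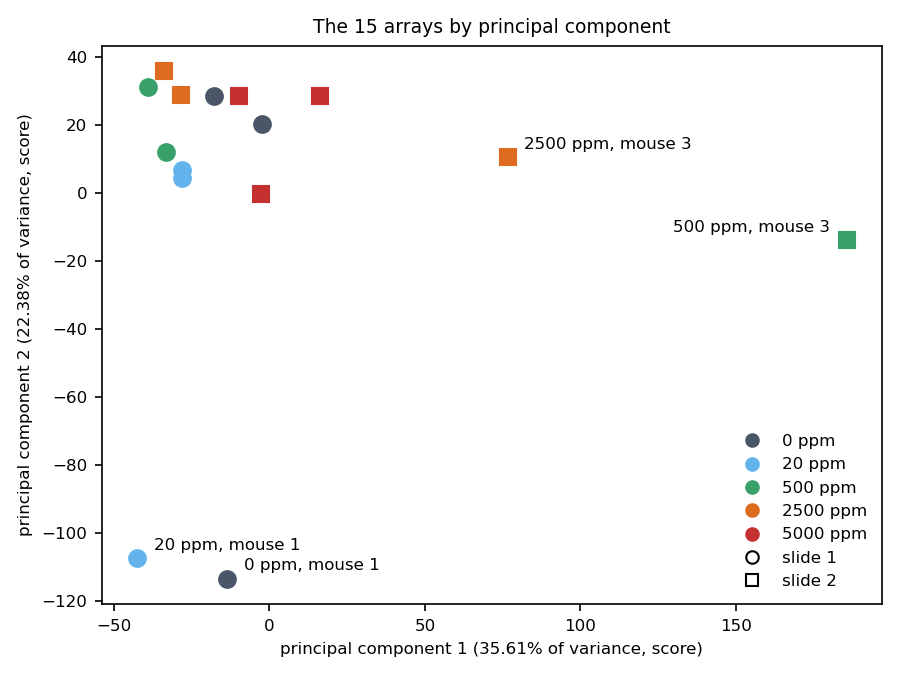
Scores of the 15 arrays on principal components 1 and 2 (x and y axes, with the percentage of variance each holds). Colour gives the dose in ppm and shape the slide, and the 4 labelled arrays lie apart from the other 11.

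The comparison of 5000 ppm with the control diet asked which lung transcripts changed at the highest dose. Gsta2, a glutathione S-transferase, rose 5.78-fold (log2 2.53 ± 0.21 SE, 3 mice against 3, adjusted p = 0.000467), and Nqo1, which reduces quinones, rose 4.54-fold (2.18 ± 0.21, adjusted p = 0.00138). Aldh3a1, an aldehyde dehydrogenase, rose 4.63-fold (2.21 ± 0.28, adjusted p = 0.014). Gpx2, a glutathione peroxidase of epithelia, rose 3.91-fold (1.97 ± 0.23), Srxn1, which repairs oxidised peroxiredoxins, 2.98-fold (1.58 ± 0.18), and Txnrd1, a thioredoxin reductase, 2.38-fold (1.25 ± 0.14), each with an adjusted p of 0.00562. Cbr3, a carbonyl reductase, rose 2.86-fold (1.51 ± 0.18, adjusted p = 0.0071). Smaller rises were those of Entpd5, a nucleotidase of the endoplasmic reticulum (2.29-fold, adjusted p = 0.017), Aox1, an aldehyde oxidase (2.12-fold, adjusted p = 0.0287), and Osgin1, an oxidative stress induced growth inhibitor (2.1-fold, adjusted p = 0.0225). For each of these 10 genes all 3 treated mice lay above all 3 controls, as the rule for naming genes requires.

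In all, 14 genes passed at 5000 ppm, 13 higher and 1 lower, and 1819 had an unadjusted p under 0.05, where 1720 are expected by chance. Besides the 10 above these were Gm10639 (5.7-fold higher) and 3 unnamed transcripts, all 4 named here after their values were seen. By the mm9 coordinates in the files, 2 unnamed ones lay on chromosome 9, at 78107225 to 78118850 (18-fold higher) and at 78104935 to 78116974 (3.16-fold higher). Their spans overlap on the same strand, so they may not be 2 separate genes. The other unnamed transcript lay on chromosome 5, at 149775338 to 149781472, and was the one that fell (log2 -0.92 ± 0.13, adjusted p = 0.0225). The count of 14 became 5 without 5000 ppm mouse 2, 6 without control mouse 1, 6 without control mouse 2, 9 without 5000 ppm mouse 1 and 22 without 2500 ppm mouse 3, and Gsta2 and Nqo1 were past the threshold in each of these fits. With array weights 62 genes were higher and 59 lower, and with the slide as a fixed block, which rests on 500 ppm mouse 3 alone, 60 were higher and 5374 lower. Under that block Gsta2 was 2.47 higher (log2, adjusted p = 0.00476) and Osgin1 was not past the threshold (adjusted p = 0.0683). With the slide as a random block 8 genes passed, all higher, among them Gsta2, Nqo1, Gpx2, Srxn1 and Txnrd1. Under that block the calls of Aldh3a1 (adjusted p = 0.193), Cbr3 (0.0654), Entpd5 (0.217), Aox1 (0.396) and Osgin1 (0.501) were lost.

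**Figure D2:**
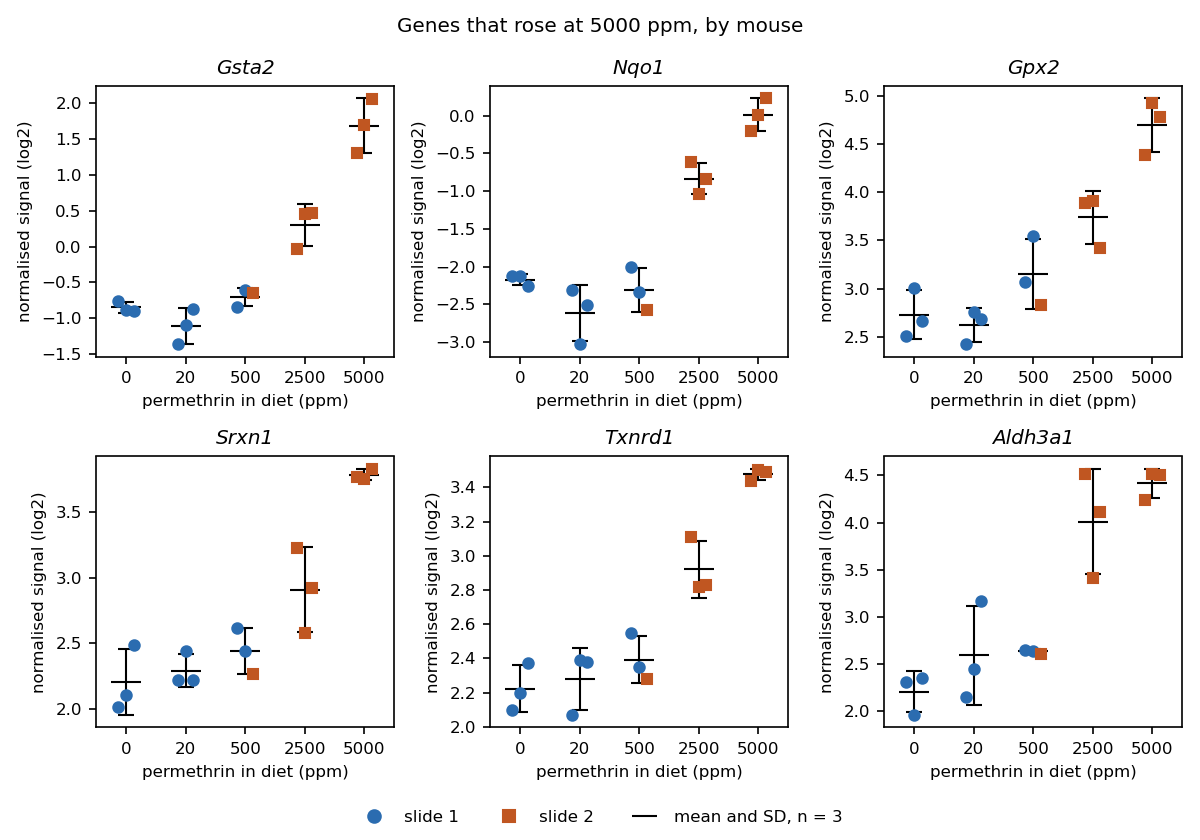
Normalised signal (log2, y axis) of 6 genes that rose at 5000 ppm, by dose in ppm (x axis). Points are single mice, with the slide as colour and shape, and bars are the mean and SD of 3 mice. By the rule that named them, all 3 mice at 5000 ppm lay above all 3 controls.

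The list of genes of the transcription factor Nrf2 and the glutathione pathway held 7 of the 14 genes called. Of its 42 measured members 7 rose over all genes and 35 did not pass. Adjusted over the list alone 21 rose. Its median was 0.41 (log2), 36 members were positive, and the list lay higher than other genes (camera adjusted p = 9.39e-30, adjusted p = 0.00213 with an estimated correlation). It was the single list at 5000 ppm, of 15 with a camera call, whose call held with an estimated correlation. Within slide 1 its median was -0.05 at 20 ppm and 0.12 at 500 ppm against control, and within slide 2 it was 0.29 higher at 5000 than at 2500 ppm. With the slide as a fixed block its mean at 5000 ppm was 0.77 (camera adjusted p = 5.22e-17), against 0.66 without it. With the array median as the scale the estimated correlation was 0.537, against 0.078, and the call with an estimated correlation was lost at 5000 ppm (adjusted p = 0.921) and on the trend (adjusted p = 0.907). Without the 4 arrays apart it was lost as well (adjusted p = 0.09 and 0.0915), and without 500 and 2500 ppm mouse 3 it was lost on the trend (adjusted p = 0.0505).

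Other drug-metabolising lists also lay higher at 5000 ppm. Each shares 1 member or more with the Nrf2 and glutathione list, Nqo1 and Gsta2 among them, so these calls are not independent of it. Of 13 targets of the aryl hydrocarbon receptor 2 rose (Nqo1 and Aldh3a1), 3 adjusted over the list alone, and the list lay higher (camera adjusted p = 2.34e-05, adjusted p = 0.263 with an estimated correlation). Cyp1a1, the target most specific to that receptor, was not past the threshold (log2 -1.06 ± 0.42, adjusted p = 0.879). Of 33 targets of the nuclear receptors CAR and PXR 1 rose (Gsta2), and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 4.64e-06, adjusted p = 0.48 with an estimated correlation). Cyp2b10, the usual marker of CAR, was 1.31-fold higher without passing (0.39 ± 0.23, adjusted p = 0.976), and it changed sign (log2 -0.04) when the mean of its probes was used. Cyp3a13 (0.28 ± 0.41), Por (0.26 ± 0.20), Nr1i3 (-0.32 ± 0.23) and Nr1i2 (0.14 ± 0.42), which encode an enzyme, its reductase and both receptors, were not past the threshold. Leaving out 1 array gave -0.06 to 0.67 for Cyp3a13, -0.11 to 0.50 for Nr1i2, 0.12 to 0.34 for Por, -0.52 to -0.20 for Nr1i3 and 0.21 to 0.52 for Cyp2b10. Among 29 other phase I enzymes of the lung Aox1 rose, 3 rose adjusted over the list alone, and the list lay higher (camera adjusted p = 0.0129, adjusted p = 0.322 with an estimated correlation).

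**Figure D3:**
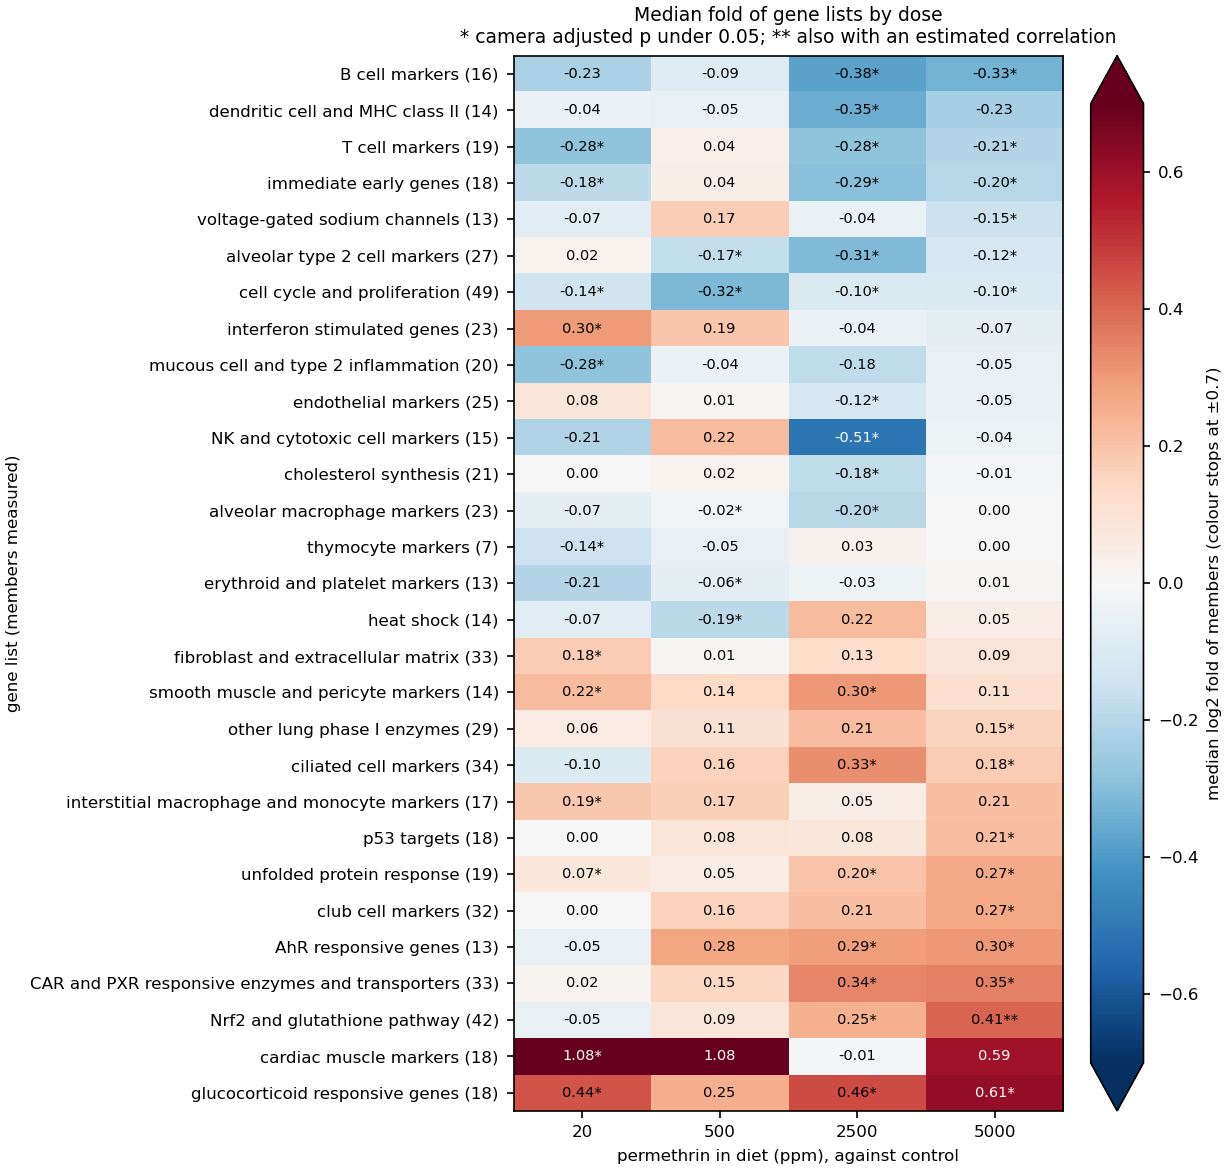
Median log2 fold of list members at each dose against control (cells, with the same value as colour), for the 29 lists with a camera adjusted p under 0.05 at 1 dose or more. The columns are the doses in ppm, the numbers beside list names are members measured, and 2 asterisks mark a call that also held with an estimated correlation, which the Nrf2 and glutathione list at 5000 ppm had.

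Markers of lung cell types were compared at 5000 ppm in the same way, and no marker named here passed. With the slide as a fixed block 3 of the 15 lists with a camera call at 5000 ppm turned to the other direction, alveolar type 2 markers (adjusted p = 0.473), T cell markers (adjusted p = 0.931) and immediate early genes (median 0.15, adjusted p = 0.00929). Club cell markers lay higher (median 0.27, 32 measured, none past the threshold over all genes and 3 higher adjusted over the list alone, camera adjusted p = 1.79e-05, adjusted p = 0.491 with an estimated correlation), although the club cell products Scgb1a1 (0.29 ± 0.19) and Cyp2f2 (0.28 ± 0.20) did not pass and Scgb1a1 changed sign under quantile normalization (-0.02). Ciliated cell markers lay higher (median 0.18, adjusted p = 0.00486, adjusted p = 0.782 with an estimated correlation), with Meig1 at 0.57 and Ccdc39 at 0.52, and Foxj1 at -0.11 (-0.29 to 0.21 with 1 array left out, against 0.43 to 0.77 for Meig1 and 0.37 to 0.61 for Ccdc39). Alveolar type 2 cell markers lay lower (median -0.12, adjusted p = 0.0131, adjusted p = 0.524 with an estimated correlation), with Lyz2 at -1.07 and Egfl6 at -0.82, whereas the surfactant gene Sftpc stood at 0.15 (-0.09 under quantile normalization). Lyz2 measured 4.56 in control mouse 1 and 4.05 in 20 ppm mouse 1, the 2 arrays apart on the second component, and from 1.24 to 2.29 in the others. With 1 array left out its fold ran from -1.54 to -0.19, the latter without control mouse 1, and that of Egfl6 from -1.05 to -0.59. B cell markers (median -0.33, adjusted p = 0.0111, adjusted p = 0.686 with an estimated correlation) and T cell markers (median -0.21, adjusted p = 0.00031, adjusted p = 0.529 with an estimated correlation) lay lower, with Fcrla at -0.60, Fcer2a at -0.53, Bcl11b at -0.71 and Themis at -0.63. With 1 array left out these ran from -0.80 to -0.41, -0.74 to -0.31, -1.06 to -0.20 (without control mouse 1) and -0.85 to -0.42 in that order.

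Stress and growth lists at 5000 ppm had no member past the threshold over all genes, and none of their calls held with an estimated correlation. The unfolded protein response lay higher (18 of 19 members positive, median 0.27, adjusted p = 2.34e-05, adjusted p = 0.491 with an estimated correlation), with 3 members higher adjusted over the list alone, Creld2 at 0.66 and Asns at 0.59 (0.42 to 0.69 with 1 array left out). Targets of p53 lay higher (16 of 18 positive, median 0.21, adjusted p = 0.00269, adjusted p = 0.529 with an estimated correlation), with Gdf15 at 0.94 (0.64 to 1.23 with 1 array left out) and Cdkn1a at 0.54 (0.34 to 0.74). Glucocorticoid responsive genes lay higher (median 0.61, adjusted p = 2.34e-05, adjusted p = 0.491 with an estimated correlation), with Hif3a at 1.10 (0.84 to 1.30 with 1 array left out) and Per1 at 0.91 (0.44 to 1.43, the lower without control mouse 1). Cell cycle genes lay lower (41 of 49 members negative or 0, median -0.10, adjusted p = 0.00269, adjusted p = 0.829 with an estimated correlation), with Pbk at -0.92 and Cenpa at -0.81, and the proliferation genes Mki67 (-0.28 ± 0.28) and Top2a (-0.36 ± 0.41) did not pass. Leaving out 1 array gave -0.55 to -0.13 for Mki67 and -0.70 to -0.06 for Top2a. With 1 array left out Pbk ran from -1.54 to -0.52 and Cenpa from -1.29 to -0.04, its value without control mouse 1. Immediate early genes (median -0.20, adjusted p = 0.0175, adjusted p = 0.686 with an estimated correlation) lay lower, with Atf3 at -0.77 and Nr4a1 at -0.62, and their median was 0.05 without control mouse 1 and 20 ppm mouse 1. With 1 array left out Atf3 ran from -1.17 to -0.17 and Nr4a1 from -0.90 to -0.19, the values nearest 0 being those without control mouse 1. Voltage-gated sodium channels lay lower (median -0.15, adjusted p = 0.0377, adjusted p = 0.529 with an estimated correlation), with Scn3b at -0.67 and Scn11a at -0.60 (0.11 with normexp). Without 1 array Scn3b and Scn11a ran from -0.89 to -0.53 and from -0.89 to -0.17. The call of the sodium channel list was kept in 4 of the alternatives followed for lists and lost in 4, with medians from -0.453 to 0.0772.

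At 2500 ppm against control limma called 0 genes, with 3111 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0864. The genes with the smallest p were Lncpint, a long noncoding RNA (log2 1.03 ± 0.16), Ltb4r2, a leukotriene B4 receptor (-1.82 ± 0.28), and Nqo1 (1.34 ± 0.21), none past the threshold. All 14 genes called at 5000 ppm had the same sign at 2500 ppm, against the same controls. The Nrf2 and glutathione list lay higher (median 0.25, 30 of 42 members positive, none past the threshold over all genes and 12 higher adjusted over the list alone, camera adjusted p = 2.04e-06), with an adjusted p = 0.244 with an estimated correlation. Leaving out 2500 ppm mouse 3, an array apart on the first component, gave 76 genes, leaving out 2500 ppm mouse 2 or 5000 ppm mouse 3 gave 1 each, and leaving out 500 ppm mouse 3 as well gave 179, an alternative chosen after seeing the data. As a fixed block the slide gave 5253 genes, 5147 of them lower, a result that rests on 500 ppm mouse 3.

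Of the 43 lists 17 had a camera call at 2500 ppm, 7 higher and 10 lower, and 0 held with an estimated correlation (fry called 1). The number was 9 without 2500 ppm mouse 1 and 9 without 2500 ppm mouse 3. With the slide as a fixed block 5 of the 17 turned to the other direction, the lower lists of alveolar macrophage, dendritic cell and MHC class II and endothelial markers, immediate early genes and cholesterol synthesis. Besides the list above, CAR and PXR targets (median 0.34, camera adjusted p = 0.0147) and aryl hydrocarbon receptor targets (0.29, adjusted p = 0.00728) lay higher, each with an adjusted p = 0.617 with an estimated correlation. NK and cytotoxic cell markers (median -0.51, adjusted p = 0.000162), markers of dendritic cells and MHC class II (-0.35, adjusted p = 0.0147) and cholesterol synthesis (-0.18, adjusted p = 0.00562) lay lower, again with an adjusted p = 0.617 with an estimated correlation. At 2500 and 5000 ppm in turn Itga2 stood at 0.93 and 0.74 and Klre1 at -0.22 and 0.60. Of these members named by their fold at 5000 ppm, Klre1 had the sign of the median of NK and cytotoxic cell markers at 2500 ppm and Itga2 did not. At 5000 ppm Itga2 ran from 0.51 to 0.89 and Klre1 from 0.34 to 0.91 with 1 array left out, and Klre1 was -0.39 under a fixed slide block. Others at 5000 ppm were H2-DMa at -0.86 and Batf3 at -0.44, and Dhcr7 at -0.74 and Mvd at -0.33, none past the threshold. Under a fixed slide block Dhcr7 stood at -1.84 (adjusted p = 0.0354). H2-DMa measured 0.99 in control mouse 1 and 1.22 in 20 ppm mouse 1, and its fold at 5000 ppm was 0.31 without these 2 arrays. Without 1 array it ran from -1.57 to 0.31, Batf3 from -0.73 to 0.09, Mvd from -0.59 to 0.11 and Dhcr7 from -0.89 to -0.55. The highest value of each was that without control mouse 1. Smooth muscle and pericyte markers lay higher (median 0.30, adjusted p = 0.0269, adjusted p = 0.617 with an estimated correlation), with Cnn1 at 1.20 and Lmod1 at 0.90 at 5000 ppm (0.82 to 1.45 and 0.73 to 1.17 with 1 array left out). Endothelial markers lay lower (median -0.12, adjusted p = 0.0456, adjusted p = 0.617 with an estimated correlation), with Aplnr at -0.92 and Lyve1 at 0.81 at 5000 ppm (-0.18 and 0.24 without control mouse 1 and 20 ppm mouse 1). The other calls at 2500 ppm were for ciliated, alveolar type 2, alveolar macrophage, B and T cell markers, cell cycle, glucocorticoid responsive and immediate early genes and the unfolded protein response, with an adjusted p from 0.244 to 0.714 with an estimated correlation.

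At 500 ppm limma called 0 genes, with 946 at an unadjusted p under 0.05 and a smallest adjusted p of 0.959. Cwc22, a splicing factor, was lower by log2 -2.65 ± 0.47, Platr22, a noncoding RNA, stood at 0.56 ± 0.12 and Ust, a sulfotransferase, at 0.86 ± 0.18, the genes with the smallest p. Within slide 1, with 2 mice at 500 ppm, Cwc22 stood at -2.75 without passing (adjusted p = 0.733). Another gene was called there, and 1 gene passed at 500 ppm without 5000 ppm mouse 3, through the shared estimate of spread. Of the 43 lists 5 lay lower and 0 higher, and 0 held with an estimated correlation or by fry. They were cell cycle genes (median -0.32, 41 of 49 members negative or 0, adjusted p = 4.06e-17, adjusted p = 0.932 with an estimated correlation), alveolar type 2 markers (-0.17, adjusted p = 7.64e-07, adjusted p = 0.257 with an estimated correlation), alveolar macrophage markers (-0.02, adjusted p = 0.028, adjusted p = 0.989 with an estimated correlation), erythroid and platelet markers (-0.06, adjusted p = 0.000138, adjusted p = 0.932 with an estimated correlation, 3 members lower adjusted over the list alone) and heat shock genes (-0.19, adjusted p = 0.0023, adjusted p = 0.989 with an estimated correlation). Values at 5000 ppm were -1.05 for Ear1, -0.66 for F7, -0.63 for Hbb-b1, 0.71 for Hspb1 and 0.46 for Hspe1. Leaving out 1 array gave -1.32 to -0.58 for Ear1, -1.07 to 0.01 for F7, -1.02 to -0.32 for Hbb-b1, 0.48 to 0.86 for Hspb1 and 0.16 to 0.64 for Hspe1, and F7 was at 0.01 without control mouse 1. The alveolar macrophage list at 500 ppm turned to the other direction without 500 and 2500 ppm mouse 3 (median -0.04, adjusted p = 0.979). The number of lists was 12 without control mouse 1, 9 without 500 ppm mouse 1, 8 without 500 ppm mouse 2 and 17 without 500 ppm mouse 3.

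At 20 ppm limma called 0 genes, with 553 at an unadjusted p under 0.05, fewer than the 1720 expected by chance. Slc6a2, the noradrenaline transporter (1.57 ± 0.33), Psg23, a pregnancy-specific glycoprotein (0.63 ± 0.15), and Tmsb15l, a thymosin (-0.92 ± 0.22), had the smallest p and an adjusted p of 1. Camera called 12 of the 43 lists, 7 higher and 5 lower, and 0 held with an estimated correlation or by fry. The higher ones were interferon stimulated genes (22 of 23 members positive, median 0.30, adjusted p = 9.38e-13, adjusted p = 0.111 with an estimated correlation), glucocorticoid responsive genes (0.44, adjusted p = 7.95e-10, adjusted p = 0.289 with an estimated correlation), fibroblast and matrix genes (0.18, adjusted p = 6.93e-06, adjusted p = 0.0694 with an estimated correlation), cardiac muscle markers (1.08, adjusted p = 3.06e-05, adjusted p = 0.627 with an estimated correlation), smooth muscle and pericyte markers, interstitial macrophage and monocyte markers and the unfolded protein response. The lower ones were T cell markers (-0.28, adjusted p = 1.01e-05, adjusted p = 0.534 with an estimated correlation), thymocyte, mucous cell and type 2 inflammation, cell cycle and immediate early genes. No member of these lists passed. At 20 and 5000 ppm in turn, Ifit3 stood at 0.60 and 0.57, Rsad2 at -0.12 and -0.60, and Myl7, a cardiac gene, at 1.36 and 1.42. Values at 5000 ppm were 1 for Nppa, -0.96 for Fcgr3, 0.88 for Cd163, -0.38 for Dntt, -1.06 for Clca1 and -0.88 for Chil4. Leaving out 1 array gave -0.88 to 1.99 for Nppa, -1.56 to 0.02 for Fcgr3, 0.505 to 1.16 for Cd163, -0.45 to -0.27 for Dntt, -3.97 to 1.19 for Clca1 and -1.20 to -0.30 for Chil4. For Myl7, Ifit3 and Rsad2 it gave 0.51 to 2.08, 0.35 to 0.71 and -0.71 to -0.41. The number of lists was 7 without 20 ppm mouse 1 and 7 without 20 ppm mouse 3.

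The direct comparison of 5000 with 2500 ppm asked whether the response grew between the 2 highest doses, on arrays of a single slide. Limma called 0 genes, with 2008 at an unadjusted p under 0.05. Gsta2 (1.39 ± 0.21), Olfr612, an olfactory receptor gene (-1.45 ± 0.24), and Lncpint (-0.91 ± 0.16) had the smallest p, with adjusted p values of 0.31, 0.348 and 0.348. At 5000 ppm Olfr612 was not well above background on any of the 3 arrays, which bounds its difference at 1.82-fold or more. As a list, in a test added after the data were seen, the Nrf2 and glutathione genes lay higher at 5000 ppm (40 of 42 members positive, median 0.29, 10 higher adjusted over the list alone, camera adjusted p = 1.41e-15, adjusted p = 0.027 with an estimated correlation). This call with an estimated correlation was lost with the array median (adjusted p = 0.951), array weights (0.197), normexp (0.0622), the deposited values (0.0624), the slide as a fixed block (0.0566) and the replicate block (0.0518). It was also lost without control mouse 2 (0.0508), 500 ppm mouse 2 (0.052) or 3 (0.0566), 2500 ppm mouse 1 (0.065), 2 (0.0556) or 3 (0.198), 5000 ppm mouse 2 (0.0708) or 3 (0.0564). The same held without 500 and 2500 ppm mouse 3 (0.686), control and 20 ppm mouse 1 (0.0964) or all 4 (0.997). CAR and PXR targets (median 0.12), alveolar type 2 (0.14) and NK and cytotoxic cell markers (0.48) also lay higher, each with an adjusted p = 0.923 with an estimated correlation. In a fit of slide 2 alone the Nrf2 and glutathione list had a camera adjusted p of 7.99e-13 and an adjusted p of 0.955 with an estimated correlation, and without 2500 ppm mouse 3 the count of genes was 11.

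The trend over dose rank asked which genes moved in the order of the doses. Of 64 genes called 39 rose and 25 fell, including all 14 called at 5000 ppm, and 3247 had an unadjusted p under 0.05. The balance of directions depended on the fit, with 231 rises and 524 falls with array weights, 59 and 98 without 500 and 2500 ppm mouse 3, 50 and 69 without the 4 arrays apart, and 79 and 5843 with the slide as a fixed block. Cxcl5, a chemokine that attracts neutrophils, rose with dose (0.64 ± 0.10 log2 per rank, adjusted p = 0.0273) and stood 5.98-fold above control at 5000 ppm. Ces1g, a carboxylesterase (3.96-fold at 5000 ppm), Kcna6, a potassium channel (2.95-fold), Ugt1a6a, which conjugates phenols with glucuronic acid (2.83-fold), Sfn, the protein 14-3-3 sigma of epithelia (2.64-fold), and Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis (2.63-fold), rose as well. Gsta2, Nqo1, Aldh3a1, Gpx2, Srxn1 and Cbr3 rose over the ranks too, with adjusted p values from 1e-04 to 0.00214. A slope over the ranks does not show a rise at each step. Within slide 1 these 6 stood from -0.445 (Nqo1) to 0.385 (Aldh3a1) at 20 ppm against control. At 500 ppm they stood there from 0.00365 (Nqo1) to 0.583 (Gpx2). Gstm1 (1.94-fold at 5000 ppm), Gstm3 (1.89-fold) and Gsta3 (1.93-fold), glutathione S-transferases abundant in the lung, passed on the trend. With the slide as a fixed block Ces1g (adjusted p = 0.331), Kcna6 (0.713), Ugt1a6a (0.347), Bgn (0.591), Gstm1 (0.0559), Gstm3 (0.082), Gsta3 (0.133) and Olfr665 (0.0707) were not past the threshold, and the slope of Kcna6 fell from 0.43 to 0.11 per rank. A random slide block kept the trend calls of Gsta2 (0.00813), Nqo1 (0.00813) and Gpx2 (0.0478). Those of Aldh3a1 (0.145), Srxn1 and Cbr3 (each 0.0901), Cxcl5, Gclc and Cwc22 (each 0.454), Sfn (0.579) and the others named here were lost. Falls were those of Cwc22 (adjusted p = 0.0169), Bgn, a proteoglycan of the extracellular matrix (1.72-fold lower at 5000 ppm, adjusted p = 0.0488), and 3 olfactory receptor genes near background. Those 3 were not well above background on any array at 5000 ppm. Olfr665 was thus at least 1.29-fold, Olfr295 at least 1.04-fold and Olfr1280 at least 1.67-fold lower there. Olfr295 had the other sign (0.03 per rank) with normexp.

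**Figure D4:**
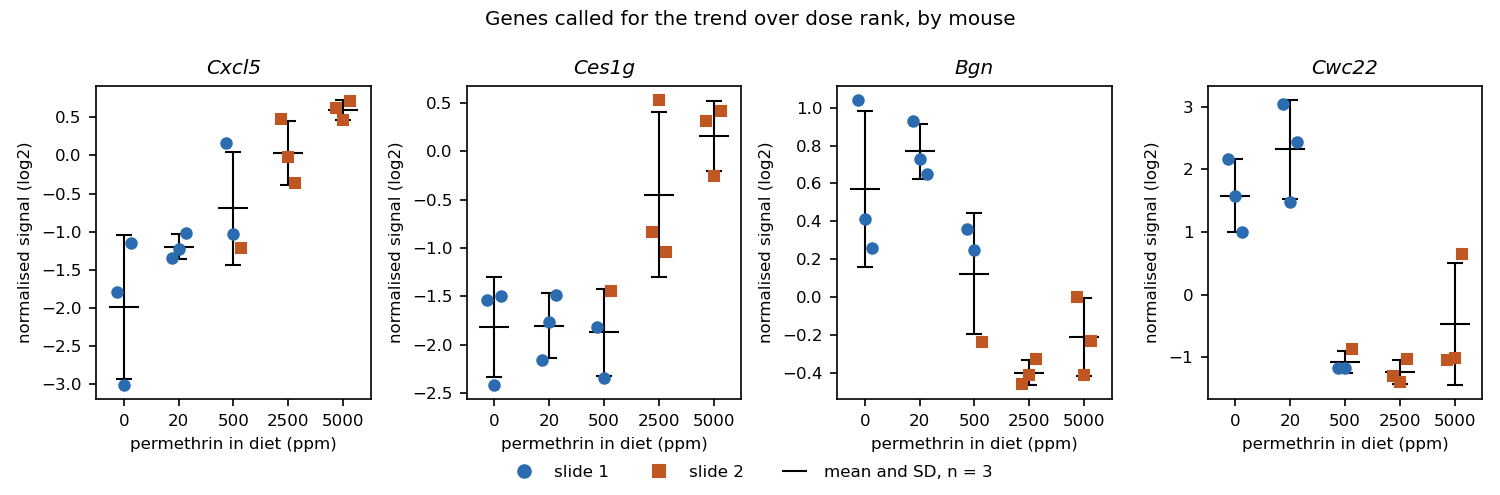
Normalised signal (log2, y axis) of 4 genes called for the trend, by dose in ppm (x axis). Points are single mice, with the slide as colour and shape, and bars are the mean and SD of 3 mice. Cwc22 lay between 1 and 3.04 in the 6 mice at 0 and 20 ppm and below in the other 9.

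Cwc22 stepped down between 20 and 500 ppm on its most abundant probe. Both other kept probes were also lower at 5000 ppm, by log2 -1.61 and -0.80. The Nrf2 and glutathione list had 11 of 42 members past the threshold on the trend, all rises, and 26 adjusted over the list alone (camera adjusted p = 1.79e-23, adjusted p = 0.00563 with an estimated correlation), the single one of 20 camera calls that held with an estimated correlation under the scaling reported (fry called 4 lists), and the number of camera calls was 13 without 5000 ppm mouse 3. Of these 20 lists 8 turned to the other direction under a fixed slide block. The lists of CAR and PXR targets (3 rose) and of aryl hydrocarbon receptor targets (3 rose) had adjusted p values of 0.505 and 0.345 with an estimated correlation. The 3 CAR and PXR targets, Gsta2, Gstm1 and Gstm3, and Nqo1 of the other list are also members of the Nrf2 and glutathione list. The F test over all 5 diets called 14 genes, 12 of them also called at 5000 ppm, with 2025 at an unadjusted p under 0.05. Leaving out 1 array moved the trend count from 64 to between 16 and 82. It was 16, 18 and 23 without control mouse 1, 2 or 3, 40, 36 and 31 without 20 ppm mouse 1, 2 or 3, 35 without 500 ppm mouse 1 or 2, 23 and 34 without 2500 ppm mouse 1 or 2, and 20, 18 and 30 without 5000 ppm mouse 1, 2 or 3. The count of the F test was 5, 6 and 9 without control mouse 1, 2 or 3, 8 and 7 without 20 ppm mouse 1 or 3, 6 without 500 ppm mouse 1 or 2, 23 without 500 ppm mouse 3 or 2500 ppm mouse 3, and 5 and 4 without 5000 ppm mouse 1 or 2.

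The doses were compared with each other through their folds against the shared control. No gene was called at 2 doses in the same direction, and 14, 13 and 7 of the 14 genes called at 5000 ppm had the same sign at 2500, 500 and 20 ppm. Across genes, which are not independent replicates, the folds at 2500 and 5000 ppm had a Pearson r of 0.637 and like signs in 72.6% of genes. The r was 0.586 for 500 and 2500 ppm, 0.568 for 500 and 5000 ppm, 0.264 for 20 and 2500 ppm, 0.247 for 20 and 5000 ppm and 0.124 for 20 and 500 ppm. Unchanged groups simulated against a shared control gave an r of 0.501 and like signs in 66.6% of genes.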

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

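Leaving out control and 20 ppm mouse 1, or 500 and 2500 ppm mouse 3, or all 4, and the slide as a random block were chosen after seeing the data. Scan date as a block was not run, since there was 1 scan day. Normexp used median signals because the files hold no mean signal. No alternative reversed any of the 10 named genes called at 5000 ppm, and the other 4 called there were not followed one by one. Among the values of named genes 1752 kept direction and side of the threshold, 196 lost the call, 22 gained one and 34 reversed. Gsta2 kept its call in all 19 alternatives followed (log2 2.28 to 2.72), which include its lowest and highest values with 1 array left out. It also kept the call in all 15 fits without 1 array, as Nqo1 did in those 15. The others called at 5000 ppm lost the call in some of these fits with the direction kept, Gpx2 and Txnrd1 in 2, Srxn1 in 3, Cbr3 in 4, Entpd5 in 5, Aldh3a1 in 6, Osgin1 in 8 and Aox1 in 9. Of the 19 alternatives followed, Nqo1 lost its call in 1 (highest limma adjusted p 0.0534). Txnrd1 lost it in 2 of the 19, Gpx2 in 4, Aldh3a1, Srxn1 and Cbr3 in 5, Entpd5 in 6, Aox1 in 9 and Osgin1 in 10. On the trend Gsta2, Nqo1, Aldh3a1, Gpx2, Srxn1 and Cbr3 kept the call in all 15 fits without 1 array. In those fits it was lost in 1 for Olfr1280, 4 for Sfn and Cwc22, 6 for Gclc and Gsta3, 7 for Gstm1 and 10 for Cxcl5. It was lost in 11 for Olfr665, 12 for Ces1g and Ugt1a6a, 13 for Kcna6 and Olfr295, 14 for Bgn and 15 for Gstm3. Of the 22 alternatives followed for the trend, Gsta2, Nqo1 and Gpx2 lost the call in 1, Srxn1 in 2 and Aldh3a1 and Cbr3 in 3. Where no reason is given, the cause was not tested.

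Counts of genes are given here for 20, 500, 2500 and 5000 ppm (0, 0, 0 and 14 as reported), 5000 against 2500 ppm (0), the trend (64) and the F test (14). A log2 fold of at least 1 as well left 3 on the trend, whose unit is a change per rank. Normexp gave 6 at 2500 ppm, 41 on the trend and 1 gene shared between doses, against 0 as reported. The median of all genes was then 0.105 at 2500 and 0.126 at 5000 ppm, against 0.0524 and 0.0404 as reported. The array median gave 4 at 500, 4 at 2500 and 9 at 5000 ppm, 39 on the trend and 4 shared, with a median of all genes of 0.105 at 5000 ppm. No filter gave 30 on the trend and 5 by the F test, and the mean of a gene's probes 40 on the trend. Empirical Bayes with a trend and robust settings gave 26 at 2500 ppm and 31 by the F test. Array weights gave 19 at 20, 986 at 2500 and 121 at 5000 ppm, 754 for 5000 against 2500 ppm, 755 on the trend and 838 by the F test. A fit of only the groups compared gave 1 at 20, 1 at 2500 and 8 at 5000 ppm. On other dose scales or ranges the trend called 39 (linear in ppm), 4 (without the 5000 ppm group) and 13 (without the control group).

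The slide as a fixed block gave 5253 at 2500 and 5434 at 5000 ppm, 5922 on the trend and 2953 by the F test, and 17 lists at 500 ppm. Its slide effect rests on the groups found on both slides, which is 500 ppm alone, with 500 ppm mouse 3 on slide 2. The slide as a random block gave 8 at 5000 ppm, 5 on the trend and 3 by the F test. The replicate number as a block over all diets gave 2 genes at 2500 ppm and 7 by the F test, and moved no other count of genes or lists by over 1.5 times. A fit of control and 20 ppm alone as pairs, chosen after seeing the data, gave 0 genes with limma (2122 at an unadjusted p under 0.05) and 11 lists.

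Without 500 and 2500 ppm mouse 3 the counts were 179 at 2500 and 30 at 5000 ppm, 13 for 5000 against 2500 ppm, 157 on the trend and 55 by the F test. Without control and 20 ppm mouse 1 they were 11 at 20 and 6 at 5000 ppm and 14 on the trend. Without all 4 they were 15 at 20 and 255 at 2500 ppm, 920 for 5000 against 2500 ppm, 119 on the trend and 213 by the F test.

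Counts of lists were 12, 5, 17 and 15 at 20, 500, 2500 and 5000 ppm and 20 on the trend. With an estimated correlation they were 0, 0, 0, 1 and 1, and by fry 0, 0, 1, 3 and 4. At 500 ppm they were 8 with normexp, 19 with array weights, 17 without 500 and 2500 ppm mouse 3, 15 without control and 20 ppm mouse 1 and 19 without all 4. At 20 ppm array weights gave 7. At 2500 ppm and on the trend they were 8 and 13 without 500 and 2500 ppm mouse 3, and 5 and 13 without all 4.

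Leaving out each array in turn gave 0 to 0 genes at 20 ppm, 0 to 1 at 500 ppm (1 without 5000 ppm mouse 3), 0 to 76 at 2500 ppm (76 without its mouse 3, 1 without its mouse 2, 1 without 5000 ppm mouse 3) and 0 to 11 for 5000 against 2500 ppm (11 without 2500 ppm mouse 3). At 5000 ppm it gave 5 to 22, with 6 without control mouse 1 or 2, 9 and 5 without 5000 ppm mouse 1 or 2 and 22 without 2500 ppm mouse 3. The trend gave 16 to 82, with 16, 18 and 23 without control mouse 1, 2 or 3, 40, 36 and 31 without 20 ppm mouse 1, 2 or 3, 35 without 500 ppm mouse 1 or 2, 23 and 34 without 2500 ppm mouse 1 or 2 and 20, 18 and 30 without 5000 ppm mouse 1, 2 or 3. The F test gave 4 to 23, with 5, 6 and 9 without control mouse 1, 2 or 3, 8 and 7 without 20 ppm mouse 1 or 3, 6 without 500 ppm mouse 1 or 2, 23 without 500 ppm mouse 3 or 2500 ppm mouse 3 and 5 and 4 without 5000 ppm mouse 1 or 2. Lists ran from 7 to 14 at 20 ppm (7 without its mouse 1 or 3), 5 to 17 at 500 ppm (12 without control mouse 1, 9, 8 and 17 without its mouse 1, 2 or 3), 9 to 24 at 2500 ppm (9 without its mouse 1 or 3), 13 to 17 at 5000 ppm and 13 to 20 on the trend (13 without 5000 ppm mouse 3).

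Reversed values at 5000 ppm (log2), none past the threshold, were Scn11a 0.109 with normexp, Scgb1a1 -0.0196 and Sftpc -0.0879 with quantile normalization, Cyp2b10 -0.0361 with the mean of probes, Por -0.0142, Nr1i2 -1.2, Foxj1 0.0389 and Klre1 -0.386 with the slide as a fixed block, Nr1i2 -0.307 with it as a random block, and Foxj1 0.0984 and Mvd 0.0167 with array weights. Without control and 20 ppm mouse 1, and without all 4 arrays, Foxj1 stood at 0.211, F7 at 0.0122, Fcgr3 at 0.0172, H2-DMa at 0.313, Batf3 at 0.0927 and Mvd at 0.111, and these were also their highest values with 1 array left out, where their lowest were -0.294, -1.07, -1.56, -1.57, -0.734 and -0.586 in the same order. With 1 array left out Cyp3a13 ran from -0.0629 to 0.673, Nr1i2 from -0.113 to 0.496, Nppa from -0.879 to 1.99 and Clca1 from -3.97 to 1.19. On the trend Olfr295 stood at 0.0283 with normexp. Signal over background limits the falls, since a gene not well above background on any array of a dose gives only a bound.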

Other observations

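The tests of slides, transferases, club cells, a variant and macrophages and the fits without 500 and 2500 ppm mouse 3 were chosen only after the result was seen. Without these 2 arrays 179 genes passed at 2500 ppm (109 higher, 70 lower), and the genes named here were chosen after their values were seen. Of 43 with a gene name 32 were lower and 11 higher, and the smallest adjusted p values were those of lower genes, Ccdc182 (log2 -2, adjusted p = 0.00726), Nmur1 (-2.38, adjusted p = 0.00726) and Ppp1r1c (-1.48, adjusted p = 0.00811). Of the enzymes that rose at 5000 ppm, Aldh3a1 (3.38-fold, adjusted p = 0.0478), Nqo1 (2.53-fold, adjusted p = 0.0351), Gpx2 (2.25-fold, adjusted p = 0.0448) and Aox1 (1.98-fold, adjusted p = 0.043) passed at 2500 ppm. Slc6a2, the noradrenaline transporter, stood 3.71-fold higher (adjusted p = 0.0343), Cdh1, the cadherin of epithelia, 2.5-fold (adjusted p = 0.0315), and the long noncoding RNAs Fendrr and Lncpint 2.11-fold and 1.99-fold (each with an adjusted p of 0.043). Ltb4r2 was 3.25-fold lower (adjusted p = 0.0165) and Cwc22 7.58-fold lower (adjusted p = 0.0448). With 500 ppm mouse 3 left out no diet lay on both slides. Slide and dose were then fully confounded for these differences between 2500 ppm and control.

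The first pattern was the rise of the Nrf2 and glutathione list with dose. All arrays at 2500 and 5000 ppm lay on slide 2, so a difference between the slides cannot make the step between these doses, whatever a test gives. On slide 2 alone the list lay higher at 5000 than at 2500 ppm (p = 0.0232 with an estimated correlation, adjusted p = 0.955). The list without its transferases still lay higher at 5000 ppm (p = 4.48e-05 with an estimated correlation, 26 of 30 members positive), which argues against probes shared between transferase copies. More club cells stay open, since the 20 club cell markers outside the xenobiotic and glutathione lists had a median of 0.17 (SD 0.335, 14 positive, camera adjusted p = 0.064, adjusted p = 0.686 with an estimated correlation), which lies within that SD of the list's 0.407. An earlier test, set before its value was seen, had compared them with the 0.958 of list members called over the list alone, but those are the top of the pattern and decide nothing. For 2500 ppm above control the slide stays open, since the list median on the 500 ppm array of slide 2 minus that on slide 1 was -0.0525 and rests on 1 array, and an effect of the diet on these enzymes stays open as well.

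The second pattern was the lower Cwc22 at 500 ppm and above. On slide 1 alone it lay lower at 500 ppm by -2.75 ± 0.458 SE, a difference within 1 slide, which a difference between the slides cannot make. Cwc22 was named for its small p at 500 ppm on arrays that include these, so the value is no separate support for a fall. The test on slide 1 replaced a first one on the same arrays, the adjusted p of 0.733, which decided nothing, and the replacement was chosen after both values were seen. For 2500 and 5000 ppm the slide stays open, since the difference of 0.309 between the 500 ppm arrays of the slides rests on 1 array. A variant carried by some of the mice could also lower the signal of its probes, and 5000 ppm mouse 3 lay 1.68 above the other 5000 ppm mice, but genotypes of this outbred stock were not measured and an effect of the diet stays open too.

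The third pattern was that control mouse 1 and 20 ppm mouse 1 lay apart, with 581 genes that on both lay above all other arrays by over 1 log2, against 149 or fewer for any other of the 105 pairs of arrays. A regional defect is argued against by a share of raised probes beside raised spots of 1.14 times their share over the array. Genomic DNA or unspliced RNA stays open. Probes named by coordinates alone differed from RefSeq-named ones by -0.0378, but genomic DNA could reach both kinds of probe. Whether the probes named by coordinates lie in introns was not looked at. The 40 macrophage markers were not raised as a set (median deviation -0.26, SD 0.776). The median excess of 2.11 cannot be set against this, since it is that of genes picked for being raised, so more macrophages are not settled. The markers moved apart, with Ly6c2, Chil3, Ear2, Apoe and C1qc at -0.414, -0.299, -0.37, -0.407 and -0.454 and Fcgr3, C1qa, F7 and C1qb at 2.54, 2.32, 1.99 and 1.34. Of the 40 markers 3 were raised on both arrays, against 581 of all 34401 genes. No other biological explanation was tested, and other cells or tissue in the samples may remain a source.

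The 6 arrays of each comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. Counts of genes as high as the real ones came from 10 splits at 20 ppm (0 by limma, 553 at an unadjusted p under 0.05, highest other 0), 10 at 500 ppm (0, 946 unadjusted, highest other 0), 10 at 2500 ppm (0, 3111 unadjusted, highest other 1), 1 at 5000 ppm (14, highest other 2) and 10 for 5000 against 2500 ppm (0, 2008 unadjusted, highest other 0). For lists they came from 5 at 20 ppm (12, highest other 21, and 11, 21 and 12 in the other splits that part all 3 like-numbered pairs), 10 at 500 ppm (5, highest other 23), 4 at 2500 ppm (17, highest other 22) and 6 at 5000 ppm (15, highest other 26). Of 100 groupings of the 15 arrays, the real one counted, 3 gave as many genes on the trend (64, highest other 425) and 4 by the F test (14, highest other 242), shares under 0.05. These groupings mix the slides, which the real one nearly follows, so the shares do not set dose apart from slide. Both others that reached the trend count, with 334 and 425 genes, put control mouse 1 and 20 ppm mouse 1 in 1 group at an end of the dose order, which points to the structure of the third pattern, though no test of this was run. For lists over dose rank 14, the real one counted, gave as many (20, highest other 24), so chance is not excluded there.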
